A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

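RNA was sequenced from 6 samples of the budding yeast Saccharomyces cerevisiae strain BY4741, a common laboratory strain of mating type a. Per the labels, 3 samples expressed NdeltaCit1-DS/AA and 3 expressed NdeltaCit1-DS/AA-H/G, and all were grown in synthetic complete medium with galactose as the carbon source. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was isolated with an RNeasy kit and libraries were made with the NEBNext Ultra II Directional kit, which marks the strand. The labels do not say whether the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. The groups share no replicate number, so samples were not paired.

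Per the submitters' processing notes, bcl2fastq 2, cutadapt 1.18, Salmon 1.2.1 and R 3.5.1 were used with genome build R64. Their order and settings, and the strand setting of the counting, are not given in the sources used here. The deposited table has 6416 rows, each a transcript with its gene name and coordinates. Its values per sample are a signal that the authors made by dividing estimated read counts by 1 scaling factor per library. This was read from the values. The smallest frequent value in each library was a step of 0.940 to 1.05, held by 104 to 130 rows, and 93.6% to 96.4% of the values under 10 steps were whole multiples of it within 0.01. Of all values above 0, 36.1% to 44.4% were whole multiples, as for estimated counts, so the values were treated as normalized values and no count model was applied. The method behind the scaling is not given in the sources used here. The authors also deposited a log2 ratio of the group means, a p-value and q-value per row, a rank as a score, and a mark for rows with q under 0.05. The test that gave their p-value is not given in the sources used here.

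Dividing by the step gave 30277566 to 32702564 estimated reads per library, and the scaled totals were 30728882 to 32121992. Among genes with at least 50 reads, replicates differed by more than counting error, so depth limits mainly the rows near the floor of a few reads. Levels are given as scaled estimated counts with the SD over the 3 samples of a group.

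Genes with a value of at least 1 in at least 3 of the 6 samples were tested, which left 6197. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with a trend on the mean level and robust variance moderation. The adjusted p is the Benjamini-Hochberg value over all tested genes, and genes under 0.05 were called. Changes are DS/AA minus DS/AA-H/G on the log2(value + 1) scale, which understates the change of low genes. The design fixed before the data were examined named this test for a file of normalized values. Its rule for named genes used CPM or TPM, for which the scaled count as a share of its column total, on the CPM scale, was used here. Before the data were examined, 47 gene lists were also fixed, and 46 with at least 3 tested members were tested with camera on the moderated statistic. Camera asks whether a list moved relative to the other genes. It used a preset inter-gene correlation of 0.01, and its p-values were adjusted over the 46 lists. It was repeated with a correlation estimated from the residuals and on ranks, and fry asked whether a list moved, on balance, 1 way. The estimate rests on 6 libraries, and its p-values are printed beside the calls. The form with an estimate also has fewer degrees of freedom than the preset form, so a larger p need not come from correlated members. The lists overlap, and a gene can stand in more than 1.

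The rule for named genes, fixed before the data were examined, had 3 parts. It took CIT1, CIT2, CIT3, UCC1 and the 4 loci deleted in BY4741. It took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 10 CPM and no overlap between the groups' samples. It took up to 3 members with the smallest p from each called list, and 2 from each of the 5 other lists with the largest absolute median change. Genes named outside this rule were chosen after their values were seen, and this is said where they appear. Gene identifiers were matched to the RefSeq table of R64, where 5811 matched and 5802 had the same start and end. Of the 708 list names, 705 were found, some of them through synonyms. The coding spans of all rows were searched against each other with BLAST+ 2.17.0. A gene sharing a stretch of at least 100 nt at 95% identity or more with another locus, as 236 rows did, is called uncertain, since estimated counts can divide such reads between copies. Overlapping genes on the same strand are also called uncertain. The kit marks the strand, but since the counting's strand setting is unknown, genes overlapping another on the opposite strand are named as such.

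The scripts were tested on simulated data with the 6 libraries' means, 6210 genes of which were tested. Of 100 genes changed by 1 on the log2 scale, 86 were recovered, and of 100 changed by 0.5, 82 were. Of 190 calls, 7 were false (3.68%). A planted list of 20 genes was called and 0 of 40 unchanged lists were. The simulated genes varied independently of each other, so the simulation does not show how the list test behaves with correlated members.

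Alternatives fixed before the data were examined were limma without the trend, quantile normalization, no filter, a mean of at least 10 CPM, pseudocounts of 0.1 and 5, no robust moderation, leaving out each sample, a fold cutoff and the other list tests. Scaling to column totals, with and without CIT1, and voom weights were added after seeing the data. Gene ontology terms were taken from the deposited table, and 1695 terms with 5 to 200 tested genes were tested for enrichment among risen and among fallen genes with a 1-sided hypergeometric test (Fisher's exact test). The background was the 5657 tested genes with a term, and p-values were adjusted over both directions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Rows for LEU2, MET17 and the mitochondrial ATP8 were not found in the table and are not analysed here.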

Results

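The transcriptomes of 2 yeast strains were compared. Both express a form of Cit1 without its presequence, the leader peptide that directs this citrate synthase into mitochondria. Citrate synthase joins acetyl-CoA and oxaloacetate into citrate at the entry of the tricarboxylic acid (TCA) cycle. The strains, named NdeltaCit1-DS/AA and NdeltaCit1-DS/AA-H/G after the form they express, are called DS/AA and DS/AA-H/G here, with 3 libraries each (DS/AA replicates 1 to 3 and DS/AA-H/G replicates 4 to 6). The labels do not spell out the substitutions behind these names. Per the series' title, the study asked how accumulation of the presequence-less protein affects the cell. Each library held 30277566 to 32702564 estimated reads, and between 6182 and 6214 rows were above 0. The first principal component of the log2 values held 61.5% of the variance and separated the strains, with scores of -21.75 to -18.10 in DS/AA and 19.34 to 20.95 in DS/AA-H/G. Correlations across genes were 0.993 to 0.995 within strains and 0.983 to 0.985 between them. Replicates differed by more than counting error, with a chi-square per gene of 4.15 to 19.2 within strains and 187 to 220 between them, so none was counted as a duplicate. In what follows, rose and fell mean a called difference of DS/AA from DS/AA-H/G, and p-values are limma's or camera's, adjusted by Benjamini-Hochberg.

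In DS/AA, many genes that make amino acids, take up sulfate, and run the steps of the TCA cycle after citrate synthase were higher than in DS/AA-H/G, while CIT1, most ribosomal protein genes, and INO1 and OPI3 of phospholipid synthesis were lower. SUL1, a sulfate permease, stood at 2502 ± 449 scaled counts against 12.5 ± 1.73 (SD, n = 3 each). ACO1, the aconitase that acts on citrate, stood at 134072 ± 5799 against 36719 ± 1538, a 3.65-fold difference. INO1, which makes inositol phosphate for phospholipid synthesis, stood at 1710 ± 20.5 against 14730 ± 2558, or 8.52-fold lower. Of 136 cytosolic ribosomal protein genes, 130 fell, and the median level was 0.82-fold that in DS/AA-H/G.

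The transcript counted as CIT1 (YNR001C, chromosome XIV, 629622 to 631061, minus strand, R64) was itself lower in DS/AA. It stood at 522165 ± 23866 scaled counts in DS/AA and 1205730 ± 11966 in DS/AA-H/G (SD, n = 3 each), a log2 change of -1.21 ± 0.03 (SE) with a limma adjusted p of 1.11e-10. It took 1.70% ± 0.0814 of the total signal in DS/AA and 3.78% ± 0.0153 in DS/AA-H/G, so the strains did not carry equal amounts of this transcript. The expressed form and the amount of this transcript thus differ together in every comparison here, and their effects cannot be told apart. The same holds for any unlabelled difference between the cultures or preparations of the strains. The row does not separate a chromosomal CIT1 transcript from that of an expressed construct. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Quantile normalization sets this row to 0 change, because CIT1 was the most abundant row in every library. URA3 (YEL021W, chromosome V, 116167 to 116970), a uracil synthesis gene that BY4741 lacks and that is widely used as a selection marker, moved with it, from 40821 ± 234 in DS/AA-H/G to 16114 ± 871 in DS/AA (log2 change -1.34 ± 0.04, limma adjusted p = 1.99e-10). HIS3, partly deleted in BY4741, was higher in DS/AA, at 1860 ± 162 against 1155 ± 97.2 (log2 change 0.69, limma adjusted p = 1.45e-05). It overlaps YOR203W by 44 nt on the same strand and is uncertain. LEU2 and MET17 were not analysed here, so the list of 4 loci deleted in BY4741 had 1 gene risen and 1 fallen (1 and 1 adjusted over the list alone) and was not tested as a list. The peroxisomal citrate synthase gene CIT2 rose from 2555 ± 238 to 4657 ± 314 (log2 change 0.87). CIT3, which encodes a further mitochondrial citrate synthase, rose by 0.62, and by 0.333 to 0.673 over the alternatives, called in each. UCC1, which encodes an F-box protein known to direct citrate synthase to degradation, was at 2342 ± 82.1 and 2448 ± 47.0 and was not called (log2 change -0.06, limma adjusted p = 0.236), although it was under quantile normalization (adjusted p = 0.0415).

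**Figure D1:**
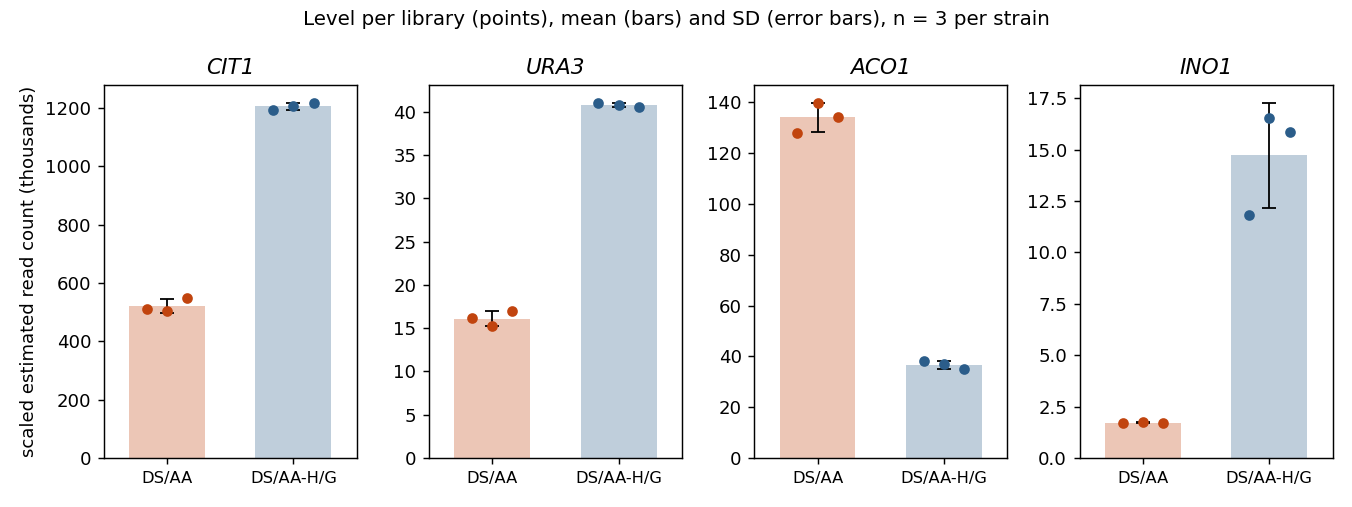
Scaled estimated read counts in units of 1000 (vertical axes, starting at 0) of CIT1, URA3, ACO1 and INO1 in the 3 DS/AA and 3 DS/AA-H/G libraries; points are libraries, bars are means and error bars are SDs. The DS/AA libraries lie below all DS/AA-H/G libraries for CIT1, URA3 and INO1 and above all of them for ACO1.

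Of 6197 genes tested, 2590 (41.8%) were called, 1368 higher and 1222 lower in DS/AA. The median absolute change of called genes was 0.246, and 2108 of them lay under 1.5-fold. Large changes were mostly rises: 217 genes rose and 21 fell by at least 1 on the log2 scale, and among the 5096 genes with a mean of 10 CPM or more (the scaled count as a share of its library, on the CPM scale) the numbers were 129 and 8. Groups did not overlap for 3268 genes (52.7%), where chance gives 10%. The balance of small changes depended on the scaling, with 52.8% of calls higher as deposited, 36.8% (1034 higher, 1778 lower) under quantile normalization and 71.1% (1841 higher, 747 lower) with equal column totals. The median change of all genes was 0.00726 as deposited and stayed within 0.1 of 0 under each of these. In the authors' deposited table, 2660 rows had q under 0.05, of which 2652 were tested here, and 2525 were called by both, all in the same direction.

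The 12 largest rises among genes at 10 CPM or more began with SUL1 (YBR294W, chromosome II, 789235 to 791814), at 184-fold (log2 change 7.52 ± 0.15, limma adjusted p = 1.22e-11). YPR145C-A, an uncharacterised reading frame (chromosome XVI, 824690 to 824926), rose from values of 12.7, 6.10 and 3.14 in the DS/AA-H/G libraries to 804 ± 134 (SD, n = 3), a log2 change of 6.76 ± 0.39. PAU2, of the seripauperin family of cell wall genes, rose by 6.26, but shares 363 nt at 96.4% identity with PAU12 and is uncertain. YMR317W rose by 4.72 and overlaps YMR316C-B on the opposite strand over 266 nt. HSP26, a small heat shock protein gene, rose from 541 ± 62.9 to 13311 ± 2476, or 24.4-fold. HES1, of the oxysterol-binding protein family, rose by 4.30, and ECM13 by 3.96. STR3, which encodes cystathionine beta-lyase of methionine synthesis, rose by 3.88 and PBI1 by 3.82. The cell wall protein gene PIR3 rose from 745 ± 21.7 to 10347 ± 972, or 13.8-fold, with a limma adjusted p of 4.90e-12. PHM8, a phosphatase gene, rose by 3.37, and PEX21, a peroxisomal import gene, by 3.23 on the log2 scale.

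Among the 12 largest falls, INO1 (YJL153C, chromosome X, 134332 to 135933) stood apart at -3.09 ± 0.13 (limma adjusted p = 6.00e-06). Further phospholipid genes were OPI3, which encodes a methyltransferase of phosphatidylcholine synthesis and fell from 24814 ± 2079 to 10652 ± 902 (log2 change -1.22), and ITR1, an inositol transporter gene, at -0.98. CIT1 and URA3 were also among them. The hexose transporter genes HXT10 and HXT6 changed by -1.38 and -1.28, and HXT6 is uncertain because it shares 1713 nt at 99.8% identity with HXT7. INA1 changed by -1.02, the membrane protein gene IZH4 went from 1436 ± 24.1 to 716 ± 19.7, and SCW11, a cell wall glucanase gene of daughter cells, changed by -0.98. PHO3, an acid phosphatase gene, changed by -0.96 and YEL073C by -0.94.

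**Figure D2:**
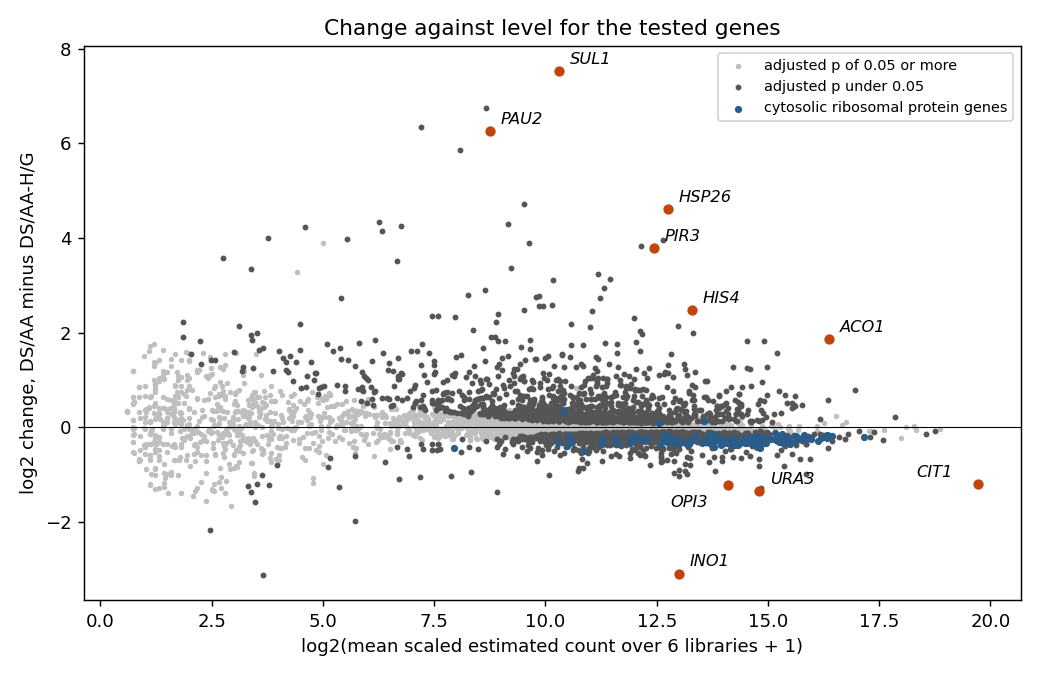
Log2 change (DS/AA minus DS/AA-H/G, vertical axis) against the log2 mean scaled estimated count plus 1 (horizontal axis) for the 6197 tested genes; dark points were called, grey points were not, and blue points are cytosolic ribosomal protein genes. Rises reach 7.52 for SUL1 while the fall of INO1 is -3.09, and CIT1 lies at the far right as the most abundant row.

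Most genes of the TCA cycle steps that follow citrate synthase rose. The fixed list leaves out CIT1, which fell, but includes CIT3, a citrate synthase gene, which rose. Of the list's 17 genes 16 rose, and 16 rose with p adjusted over the list alone. ACO1 led (YLR304C, chromosome XII, 735212 to 737548; log2 change 1.87 ± 0.04, limma adjusted p = 2.08e-11), with IDH2 at 1.83 and IDH1 at 1.82, which encode the isocitrate dehydrogenase subunits, and FUM1, the fumarase gene, at 1.28. IDH2 overlaps IRC14 on the opposite strand. The succinyl-CoA ligase gene LSC1 did not pass (0.01). The list's median change was 0.46 (camera adjusted p = 3.31e-23, but adjusted p = 0.199 with an estimated correlation). Of 6 retrograde targets, genes that answer to mitochondrial state, 4 rose and PYC1 fell, in both adjustments (4 rose and 1 fell adjusted over the list alone), with a median of 1.35. PYC1 was not called with equal column totals (adjusted p = 0.0504). DLD3, a frequent reporter of this pathway, was at 0.07 and did not pass. The list was called (camera adjusted p = 1.15e-16, adjusted p = 0.199 with an estimated correlation), and ACO1, IDH1, IDH2 and CIT2 are also in the other lists of this paragraph. Of 16 glyoxylate cycle and gluconeogenesis genes 11 rose and 0 fell, and the counts were 11 and 0 adjusted over the list alone. IDP2, the cytosolic isocitrate dehydrogenase gene, rose 6.63-fold, PCK1 of gluconeogenesis 5.90-fold, and MDH2 by 0.85 on the log2 scale, while ICL1, the isocitrate lyase gene, was at -0.11 and did not pass, except under quantile normalization (adjusted p = 0.0129), where 2 members of the list fell. That list's median was 0.58 (camera adjusted p = 1.02e-10, adjusted p = 0.199 with an estimated correlation). PYC1, DLD3, LSC1 and ICL1 were singled out after their values were seen.

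Genes of amino acid synthesis rose across most branches. All 8 lysine genes rose, also with p adjusted over the list alone (8 of 8), with LYS1 at 1.34, LYS9 at 1.32 and LYS2 at 0.76 on the log2 scale (median 0.69, camera adjusted p = 4.13e-13, adjusted p = 0.199 with an estimated correlation). Of 10 arginine genes 9 rose (9 adjusted over the list alone), among them ARG7 at 1.15, CPA1 at 0.58 and ARG5,6 at 0.63, the last overlapping YER068C-A on the opposite strand (median 0.62, camera adjusted p = 1.54e-05, adjusted p = 0.337 with an estimated correlation). Of 6 histidine genes 5 rose and HIS6 fell (5 and 1 adjusted over the list alone), led by HIS4, which rose from 3067 ± 177 to 17093 ± 1719, or 5.56-fold, with HIS1 at 1.13 and HIS5 at 1.12 (camera adjusted p = 2.18e-08, adjusted p = 0.29 with an estimated correlation). HIS6 was not called with equal column totals, with or without CIT1 (adjusted p = 0.146 and 0.0658). Glutamate and glutamine genes had 4 of 6 risen (4 adjusted over the list alone), with GDH1 at 0.67, GLN1 at 0.56 and GLT1 at 0.36 (camera adjusted p = 0.000681, adjusted p = 0.199 with an estimated correlation). In the aspartate family 5 of 8 rose and HOM6 fell (5 and 1 adjusted over the list alone), with AAT2 at 1.23, ASN1 at 0.88 and HOM3 at 0.76 (camera adjusted p = 5.33e-06, adjusted p = 0.382 with an estimated correlation, and 0.0535 with camera on ranks). Of 14 aromatic amino acid genes 11 rose and 2 fell (11 and 2 adjusted over the list alone), with ARO3 at 0.58, ARO1 and TRP5 both at 0.44 (camera adjusted p = 0.00251, adjusted p = 0.366 with an estimated correlation). The branched-chain list was not called (camera adjusted p = 0.409, adjusted p = 0.692 with an estimated correlation), although 6 of its 11 genes rose, ILV2 by 0.58 and ILV6 by 0.40, and 2 fell (6 and 3 adjusted over the list alone). HIS6 and HOM6 were singled out after their values were seen.

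The sulfur and methionine list held SUL1, the largest rise. Of its 23 genes 16 rose and 2 fell (16 and 4 adjusted over the list alone), with a median of 1.15. Besides SUL1 and STR3, the sulfate permease gene SUL2 rose 5.96-fold and MET10, of sulfite reductase, 2.35-fold. SAM2, an S-adenosylmethionine synthetase gene, fell by 0.93, and CYS4, the cystathionine beta-synthase gene, by 0.61, both singled out after their values were seen. The list was called (camera adjusted p = 1.10e-13, adjusted p = 0.361 with an estimated correlation).

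Nucleotide synthesis genes were divided. Of 17 purine genes 12 rose and 4 fell (12 and 4 adjusted over the list alone). ADE17 rose 4.09-fold, ADE2 by 0.67 and ADE3 by 0.45 on the log2 scale, while the 4 that fell were IMD2, IMD3, IMD4 and GUA1, which make guanine nucleotides and were singled out after their values were seen. The list was called (camera adjusted p = 0.0228, adjusted p = 0.438 with an estimated correlation), but not by limma without a trend (camera adjusted p = 0.0775). Of 8 pyrimidine genes 5 rose and URA7 fell (5 and 2 adjusted over the list alone). URA10 stood at 1.07, URA1 at 0.65 and URA2 at 0.46 (median 0.23, camera adjusted p = 0.0102, adjusted p = 0.261 with an estimated correlation, and 0.0831 with camera on ranks).

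Lipid genes went both ways. Of 24 ergosterol genes 19 rose and HMG2 fell (19 and 1 adjusted over the list alone), with ERG25 rising 2.41-fold, ERG1 1.81-fold and ERG5 1.66-fold (median 0.30, camera adjusted p = 4.42e-08, adjusted p = 0.29 with an estimated correlation). HMG2 was singled out after its value was seen. Fatty acid synthesis genes fell, 9 of 11, while ACS2 and OLE1 rose (9 and 2 adjusted over the list alone). ACC1, which encodes acetyl-CoA carboxylase, fell from 45435 ± 1638 to 30408 ± 519 (log2 change -0.58, limma adjusted p = 7.78e-08), and the elongase genes ELO3 (YLR372W) and ELO2 (YCR034W) stood at -0.47 and -0.46. This list's median was -0.36 (camera adjusted p = 2.08e-05, adjusted p = 0.199 with an estimated correlation). Under quantile normalization the median was -0.24 and the list was still called (camera adjusted p = 0.00152). Peroxisomal beta-oxidation genes rose, 10 of 12 (11 adjusted over the list alone), with FOX2 at 1.27, PEX11 at 0.62 and SPS19 at 0.61, the last overlapping YNL203C on the opposite strand (median 0.57, camera adjusted p = 0.000253, adjusted p = 0.29 with an estimated correlation). ACS2 and OLE1 were singled out after their values were seen.

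Most cytosolic ribosomal protein and translation factor genes fell by small amounts. Of 136 cytosolic ribosomal protein genes 130 fell and 2 rose (132 and 3 adjusted over the list alone), with a median of -0.29 and an interquartile range of -0.33 to -0.24. The list was called (camera adjusted p = 2.30e-30, adjusted p = 0.199 with an estimated correlation), and 126, 122 and 127 members fell under quantile normalization, equal column totals, and equal totals without CIT1. RPS16B stood at -0.38 and RPS18A at -0.37; RPS11B, at -0.42, is uncertain because it shares 428 nt with RPS11A. The 2 that rose were RPL15B and RPL9B, singled out after their values were seen. Of 116 ribosome biogenesis genes 61 fell and 0 rose (69 and 0 adjusted over the list alone), with NOG2 at -0.36, NOP13 at -0.30 and ESF1 at -0.20. NOG2 holds the small RNA gene snR191 on the same strand and is uncertain, and NOP13 overlaps YNL174W on the opposite strand. The median was -0.14 (camera adjusted p = 6.43e-05, adjusted p = 0.45 with an estimated correlation, 0.0872 with fry), and with equal column totals 25 members fell. Of 35 translation factor genes 28 fell and CAM1 rose (31 and 1 adjusted over the list alone), with TEF4 at -0.39, TIF34 at -0.25 and TIF11 at -0.22 (camera adjusted p = 0.000192, adjusted p = 0.361 with an estimated correlation), and 16 fell with equal column totals. Of 73 mitochondrial ribosomal protein genes 5 rose and 1 fell (1 and 0 adjusted over the list alone). Their median was 0.023 and their mean 0.0137, while camera's direction was down (camera adjusted p = 0.773, adjusted p = 0.924 with an estimated correlation), and the count turned to 2 risen and 16 fallen under quantile normalization and to 20 risen and 0 fallen with equal column totals. CAM1, an elongation factor gene, was singled out after its value was seen.

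Genes of stress and of the cell wall differed from list to list. Of 37 general stress genes 24 rose and 5 fell (26 and 6 adjusted over the list alone), with MOH1 at 2.34, HSP12 at 2.14 and NQM1 at 1.52 besides HSP26. HSP12, which encodes a membrane-associated stress protein, rose from 2968 ± 11.5 to 13114 ± 1367. Those that fell were HXK1, PGM2, GSY1, GPH1 and GSY2, of sugar phosphorylation and glycogen metabolism, singled out after their values were seen (median 0.51, camera adjusted p = 1.82e-06, adjusted p = 0.393 with an estimated correlation). Of 13 cell wall integrity genes 11 rose (11 adjusted over the list alone), with NCW2 at 1.54 and GSC2 (FKS2), a glucan synthase gene, at 0.98 after PIR3 (median 0.83, camera adjusted p = 5.99e-22, adjusted p = 0.199 with an estimated correlation). Autophagy genes rose, 11 of 14 (11 adjusted over the list alone), ATG41 by 2.80, ATG8 by 1.16 and ATG1 by 0.65 (median 0.26, camera adjusted p = 0.00197, adjusted p = 0.199 with an estimated correlation), and under quantile normalization 7 rose, with a median of 0.16. Heat shock chaperone genes moved both ways, 13 up and 7 down of 27 (14 and 8 adjusted over the list alone), with SSE2 at 0.92 and SSA3 at 0.60 and the abundant SSA1, SSA2 and HSC82, singled out after their values were seen, at -0.25, -0.36 and -0.28. This list was not called (camera adjusted p = 0.0692, adjusted p = 0.67 with an estimated correlation), though it was under quantile normalization (camera adjusted p = 0.00769), equal column totals with and without CIT1 (0.0344 and 0.0466), without robust moderation (0.0316), and without DS/AA replicate 2, DS/AA replicate 3 or DS/AA-H/G replicate 5 (0.0223, 0.0392 and 0.0495). Its median of 0.14 ran from 0.081 to 0.17 without 1 library. Of 13 unfolded protein response genes 9 fell (9 adjusted over the list alone), KAR2 by 0.34, SIL1 by 0.31 and SCJ1 by 0.27 on the log2 scale. That call (camera adjusted p = 0.023, adjusted p = 0.401 with an estimated correlation) ended without DS/AA replicate 3 (camera adjusted p = 0.0566). Of 35 proteasome genes 20 fell and RPN4 rose (23 and 1 adjusted over the list alone), with RPT6 at -0.20, RPN10 at -0.17 and PRE9 at -0.16 (median -0.10, camera adjusted p = 0.00945, adjusted p = 0.351 with an estimated correlation). With equal column totals 6 proteasome genes fell, and under quantile normalization the list was not called (camera adjusted p = 0.103). Oxidative stress genes, with 5 risen and 4 fallen of 19 (5 and 4 adjusted over the list alone), were not called (camera adjusted p = 0.28, adjusted p = 0.591 with an estimated correlation), and their median of 0.040 turned to -0.0055 under quantile normalization and to 0.094 with equal column totals, where 8 rose, and ran from 0.019 to 0.058 without 1 library. Drug resistance and mitoCPR genes were not called either, with 5 risen and 3 fallen of 11 (5 and 3 adjusted over the list alone; camera adjusted p = 0.712, adjusted p = 0.485 with an estimated correlation), of which 7 rose and 1 fell with equal column totals. RPN4, which encodes a transcription factor for proteasome genes, was singled out after its value was seen.

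Of 35 nuclear-encoded respiratory chain genes 20 rose and 0 fell (24 and 0 adjusted over the list alone). The external NADH dehydrogenase genes NDE2 and NDE1 rose by 1.27 and 0.68, and COR1 by 0.22 on the log2 scale (median 0.14, camera adjusted p = 0.00154, adjusted p = 0.339 with an estimated correlation). Of 7 mitochondrially encoded genes 0 were called at any adjustment, including adjusted over the list alone, with COX1 at -0.36 (limma adjusted p = 0.0679) and OLI1 at -0.69 (limma adjusted p = 0.0859). COX1 overlaps AI5_ALPHA on the same strand and is uncertain, and mitochondrial rows held at most 0.0102% of any library's signal (camera adjusted p = 0.552, adjusted p = 0.614 with an estimated correlation). COX1 and OLI1 were called under quantile normalization (adjusted p = 0.00251 and 0.0179), COX1 also without DS/AA replicate 2 (0.0141) or DS/AA-H/G replicate 4 (0.0464), and OLI1 without DS/AA-H/G replicate 6 (0.0369). The list's median of -0.36 rests on DS/AA replicate 1, without which it was 0.072. Mitochondrial import genes, 2 up and 9 down of 28 (2 and 9 adjusted over the list alone), were not called (camera adjusted p = 0.162, adjusted p = 0.351 with an estimated correlation), and their counts turned to 5 up and 1 down with equal column totals and to 1 up and 15 down under quantile normalization.

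Sugar genes were mixed. In the galactose regulon 6 of 8 fell (6 adjusted over the list alone), with GCY1 at -0.47, GAL3 at -0.39 and GAL7 at -0.21 (median -0.22, camera adjusted p = 0.00245, adjusted p = 0.344 with an estimated correlation). GCY1 overlaps YOR121C on the opposite strand. Hexose transporter genes rose in 5 of 10 and fell in 2 (5 and 2 adjusted over the list alone). HXT2 rose from 585 to 4484 scaled counts and HXT5 from 235 to 1607, with HXT4 at 0.94 on the log2 scale. The call (camera adjusted p = 0.00282, adjusted p = 0.401 with an estimated correlation) ended without DS/AA replicate 2 (camera adjusted p = 0.078) and with camera on ranks (0.123). Pentose phosphate genes fell in 4 of 7, and ZWF1, singled out after its value was seen, rose (4 and 1 adjusted over the list alone). GND1, of 6-phosphogluconate dehydrogenase, overlaps YHR182C-A on the opposite strand and changed by -0.67, SOL3 by -0.47 and TAL1 by -0.39 (median -0.19, camera adjusted p = 0.000944, adjusted p = 0.29 with an estimated correlation). Glycolysis and fermentation genes, 5 up and 9 down of 21 (6 and 9 adjusted over the list alone), were not called (camera adjusted p = 0.552, adjusted p = 0.757 with an estimated correlation), with a median of -0.029, a mean of 0.0921 and a camera direction of down. With equal column totals their median was 0.026, with 7 up and 6 down, and without 1 library it ran from -0.045 to -0.021.

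**Figure D3:**
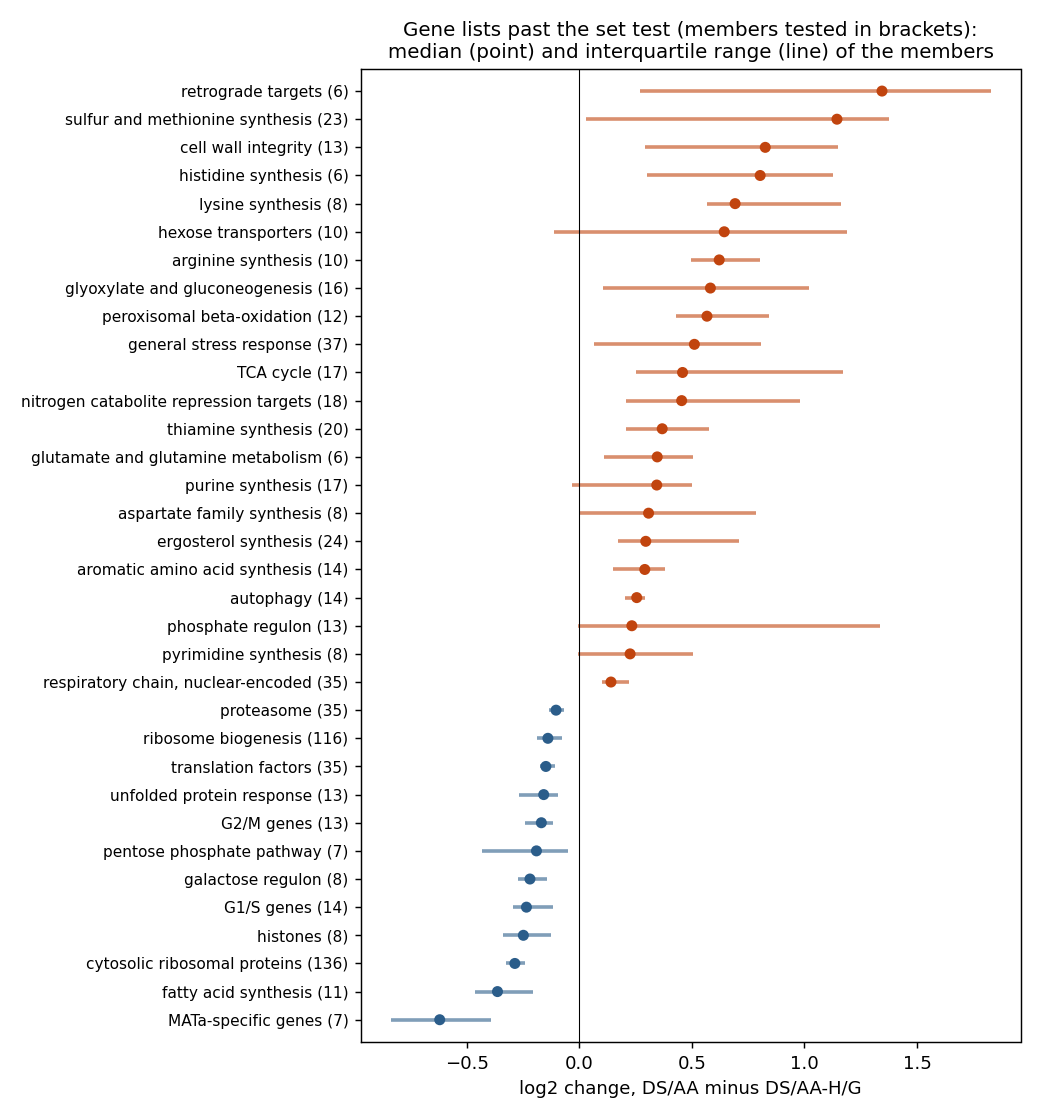
Median log2 change (points; DS/AA minus DS/AA-H/G, horizontal axis) and interquartile range (lines) of the members of the 34 called gene lists, with the number of tested members in brackets; 22 lists moved up (orange) and 12 down (blue). Medians run from -0.62 for MATa-specific genes to 1.35 for retrograde targets.

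Nutrient genes rose in several regulons. Of 18 nitrogen catabolite repression targets 14 rose and PUT2 fell (14 and 1 adjusted over the list alone), with GAP1, the general amino acid permease gene, at 1.05 and the arginine breakdown genes CAR1 and CAR2 at 1.04 and 1.03 (median 0.46, camera adjusted p = 6.74e-07, adjusted p = 0.199 with an estimated correlation). CAR2 overlaps YLR437C-A on the opposite strand, and PUT2 was singled out after its value was seen. Phosphate genes rose in 6 of 13 (8 adjusted over the list alone), with the phosphate transporter genes PHO84 at 1.55 and PHO89 at 1.34 after PHM8 (median 0.23, camera adjusted p = 0.00578, adjusted p = 0.199 with an estimated correlation). Under quantile normalization 4 phosphate genes rose and 1 fell, with a median of 0.042, and the list was still called (camera adjusted p = 0.0138). Of 20 thiamine genes 15 rose and PHO3 fell (16 and 2 adjusted over the list alone), with THI6 at 0.29, and SNZ3 at 0.61 and SNZ2 at 0.51, which share 897 nt at 99.3% identity and are uncertain. The counts and the list test treat such near-identical members as separate genes. The thiamine call (camera adjusted p = 0.0233, adjusted p = 0.199 with an estimated correlation) ended under quantile normalization (8 risen and 2 fallen, camera adjusted p = 0.156), at 10 CPM or more (0.0826) and without DS/AA replicate 3 (0.0538). Iron genes, 13 up and 3 down of 27 (13 and 3 adjusted over the list alone), were not called (camera adjusted p = 0.0659, adjusted p = 0.408 with an estimated correlation), except without DS/AA replicate 1 (camera adjusted p = 0.0221) and with voom weights (0.0444). Their median was 0.13, and 0.035 under quantile normalization. Zinc genes were not called either, with 1 of 5 fallen (1 adjusted over the list alone; camera adjusted p = 0.49, adjusted p = 0.554 with an estimated correlation), 3 under quantile normalization and 0 with equal column totals.

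How many cell cycle and mating genes fell depended on the scaling. All 8 histone genes fell, 8 adjusted over the list alone, with HTB2 at -0.35 and HTA1 at -0.33; HHF2, at -0.36, shares 312 nt at 97.4% identity with HHF1 and is uncertain (camera adjusted p = 0.00382, adjusted p = 0.298 with an estimated correlation). With equal column totals 4 histone genes fell, and under quantile normalization 5. Of 14 G1/S genes 10 fell (10 adjusted over the list alone), with the cyclin gene CLN2 at -0.44, RNR1 at -0.23, and POL30, which overlaps YBR089W on the opposite strand, at -0.35 (camera adjusted p = 0.00377, adjusted p = 0.316 with an estimated correlation). Of 13 G2/M genes 9 fell (9 adjusted over the list alone), with CLB2 and CDC20 both at -0.33 and KIN3 at -0.27 (camera adjusted p = 0.00945, adjusted p = 0.351 with an estimated correlation). With equal column totals 8 G1/S and 6 G2/M genes fell, and under quantile normalization 12 and 10. Of 7 MATa-specific genes, expressed in cells of the mating type of BY4741, 5 fell (5 adjusted over the list alone). BAR1 was at -0.71, the receptor gene STE2 at -0.62 and STE6 at -0.32. The list's median was -0.62 (camera adjusted p = 0.000944, adjusted p = 0.234 with an estimated correlation). With equal column totals 4 fell, and under quantile normalization 6. Markers of the other mating type were not called as a list (camera adjusted p = 0.49, adjusted p = 0.438 with an estimated correlation). Of 4 MATalpha-specific genes 2 rose (2 adjusted over the list alone), SAG1 by 0.25 and STE3 by 0.31, and STE3, which overlaps YKL177W on the opposite strand, was not called under quantile normalization (adjusted p = 0.583). Meiosis genes rose in 3 of 10 (3 adjusted over the list alone), with IME1 at 0.41 and IME2 at 0.42, were not called as a list (camera adjusted p = 0.51, adjusted p = 0.393 with an estimated correlation), and had a median of 0.18 that turned to -0.10 under quantile normalization, where IME2 was not called (adjusted p = 0.114), and ran from 0.089 to 0.28 without 1 library.

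Of the 46 lists tested, 34 were called with camera's preset correlation. In the other divisions of the 6 libraries into 3 and 3, where 0 genes were called, the same test called 9 to 23 lists. Those divisions have libraries of both strains on both sides, so part of the strain difference stays in them. With an estimated correlation 0 were called, 10 had an unadjusted p under 0.05, and adjusted p over the called lists ran from 0.199 to 0.45, while fry called 40 and camera on ranks 32. Fry added the heat shock chaperone, drug resistance, oxidative stress, mitochondrial import, iron, MATalpha-specific and meiosis lists, and ranks added mitochondrial import (camera adjusted p = 0.0298). Ribosomal RNA rows held 0.432% ± 0.099 of the signal in DS/AA and 0.345% ± 0.0144 in DS/AA-H/G (SD, n = 3 each), a difference smaller than the SD in DS/AA.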

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

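Scaling to column totals and voom weights were chosen after the data were seen; the other alternatives were planned. The count of called genes ran from 2009 to 2576 when a library was left out (1106 to 1317 higher, 903 to 1259 lower), and from 2188 to 2812 under the other alternatives without a fold threshold. With equal column totals the lower genes numbered 747, because equal totals scale down the DS/AA-H/G libraries, whose totals were larger. At an absolute log2 change of at least 1 there were 238 genes (217 higher, 21 lower), and against a minimum of 1.5-fold there were 243 (215 higher, 28 lower); higher thresholds explain these by construction. CIT1 lay between -1.25 and -1.18 without a library and at 0 under quantile normalization, which fixes the most abundant row. Called lists numbered 33 to 35 without a library, 40 with fry, 32 with camera on ranks and 0 with an estimated correlation. A high correlation between members is not the reason for every list. The glyoxylate and gluconeogenesis list and the phosphate list had estimated correlations of 0.0087 and -0.00019, under the preset of 0.01. Both still had a camera adjusted p of 0.199 with the estimate. The form with an estimate also has only the few degrees of freedom that 6 libraries leave. The preset form takes them from the number of genes. How much of the loss this accounts for was not tested. Camera's direction turned, with medians of -0.021 for glycolysis under quantile normalization and 0.034 for mitochondrial ribosomal proteins without DS/AA replicate 1, and 0.023 for the latter with an estimated correlation, fry and ranks. Without DS/AA-H/G replicate 6 the latter median was 0.0052. Neither list was called, and the cause was not tested. Of 134 named genes besides CIT1, 134 kept their direction and call with either pseudocount, without the trend and without robust moderation. Under quantile normalization 129 did, and 0 reversed. At 10 CPM or more 129 could be tested and kept theirs. No count model, size factors or TPM fit were run, since the deposited values are neither counts nor TPM. Only the voom weights used estimated reads, obtained by dividing by the step. No paired analysis was possible because the groups share no replicate numbers. Depth limits rows near the floor of a few reads, such as COX2 and COX3.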

Other observations

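All tests in this part were chosen after the data were seen, except those on reads shared between near-identical genes and on other splits of the samples, whose predictions were written before their results.

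Among 1695 gene ontology terms, 51 were enriched among risen and 68 among fallen genes. These p-values treat genes as independent, which they are not. Beyond the fixed lists, more phospholipid synthesis genes fell than rose: 15 of 28 fell, 4 rose and 9 did not pass (median -0.19, hypergeometric adjusted p = 0.00768), and 9 of 11 genes of phosphatidylcholine synthesis fell with 1 risen (median -0.29, adjusted p = 0.00207). Besides INO1 and OPI3 these include CHO1, the phosphatidylserine synthase gene, at -0.78, PSD1, a phosphatidylserine decarboxylase gene, at -0.79, CHO2, a methyltransferase gene, at -0.74, and CPT1 at -0.61. INO2 and INO4, whose products activate genes of this pathway, were at -0.33 and -0.24, and the repressor gene OPI1 was at -0.25. INO4 was not called with equal column totals (adjusted p = 0.061). PCT1, the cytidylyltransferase gene of the alternative route to phosphatidylcholine, rose by 0.16. The direction of both terms held with equal column totals (14 and 8 fallen) and under quantile normalization (16 and 8 fallen).

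Of 17 genes annotated as structural constituents of the cell wall 10 rose and 0 fell (median 0.33, hypergeometric adjusted p = 0.0422), with TIR1 at 1.91, SED1 at 0.79 and HSP150 at 0.57 on the log2 scale, while the abundant CCW12 was at -0.07 and did not pass. SED1, HSP150, PIR3, NCW2, CWP1, PIR1 and CIS3 are also in the cell wall integrity list, so the term partly repeats that list. Of the 8 genes of the V1 domain of the vacuolar ATPase, 7 fell by small amounts (median -0.15, adjusted p = 0.00675), VMA5 by 0.19 and VMA10 by 0.21 on the log2 scale, and 5 fell with equal column totals. Of 42 genes of protein N-linked glycosylation 21 fell and 7 rose (adjusted p = 0.00207), and 13 fell and 9 rose with equal column totals. Per chromosome, the median change of nuclear genes lay between -0.0203 and 0.0557, and no chromosome moved as a whole by as much as a gained copy would give.

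CIT1 and URA3 were lower in DS/AA by 1.21 and 1.34 on the log2 scale. The median change of all genes was 0.00726. The values were already scaled, which can by itself bring this median near 0, so it cannot decide whether the scaling was right. It shows that both genes fell relative to the typical gene. With equal column totals CIT1 was at -1.15. A pyrimidine response that lowered the pathway as a whole would lower its other genes, whose median was 0.226. A response of URA3 alone was not tested. Whether both transcripts come from 1 introduced construct at a different dose stays open. The log2 ratio of CIT1 to URA3 differed between the strains by 0.134 ± 0.022 (SE), but this is only the difference of the falls themselves and decides nothing. The expressed forms, named by the design, stay open as untested, as does any unlabelled difference between the strains' cultures or preparations.

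Cytosolic ribosomal protein genes were lower in DS/AA (median -0.29). Length was taken as the span from start to end on the chromosome, with any introns. Since 895 other genes matched on this span had a median of 0.0302, the span is an unlikely cause. The length of the spliced transcript was not matched and stays open. The list lay 0.251 below 650 other genes matched on level (difference -0.251), so a trend with level does not account for it. The bootstrap SD of this difference, 0.0102, comes from resampling genes as if independent. It does not measure the spread between libraries. With equal column totals the median was -0.231. The totals were 30728882 to 30796672 in DS/AA and 31761853 to 32121992 in DS/AA-H/G. They lie too close for this rescaling to remove the fall, so it cannot decide about scaling. A scaling factor common to all genes would also lower the level-matched genes, whose median was -0.0342. That argues against such a factor as the source of the fall. The expressed form, named by the design, stays open as untested. So does the lower amount of CIT1 transcript in DS/AA, which cannot be told apart from the form. Any unlabelled difference between the cultures or preparations of the strains stays open too.

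Large rises outnumbered large falls, 217 to 21. At 10 CPM or more the ratio was 16.1, so low depth is not the source. With the median change subtracted the counts were 215 and 21, but that median, 0.00726, is too small to move them much. Under quantile normalization they were 163 and 34, a ratio of 4.79. The excess thus shrank but stayed, and scaling may account for part of it. Among genes sharing no near-identical stretch the counts were 198 and 17, a ratio of 11.6, so shared reads do not account for the excess. No biological explanation was tested. The expressed form and the lower amount of CIT1 transcript in DS/AA stay open and cannot be told apart. Nor can either be told apart from any unlabelled difference between the cultures or preparations of the strains.

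The 6 samples can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real one, as many as 2590 genes were called, and the highest of the others gave 0. For lists, 1 of the 10, again the real one, gave as many as 34, and the others gave 9 to 23 although 0 genes were called in them. Each of the others has libraries of both strains on both sides. The strain difference there widens the spread and partly stays in the contrast, so these counts are not those of unchanged samples.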
